A study of Bos taurus with 189 samples.

How the data were processed

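RNA sequencing libraries of 4 tissues (rumen epithelium, liver, muscle and backfat, the fat layer under the skin) from 48 beef steers were compared. Per the labels, total RNA was isolated with a mirVana kit from rumen epithelium, liver and muscle and with an RNeasy Lipid kit from backfat, and RNA with an integrity number above 7 was used. The labels name TopHat2 2.0.9, SAMtools 1.1, HTSeq 0.6.1 and the cattle assembly UMD3.1, without giving their order, the annotation release or the strand setting. The gene files hold raw counts of reads per Ensembl gene as deposited by the authors, not normalised, with 24616 gene IDs in each of 189 files. All files except 2 of rumen epithelium also give the records that were not assigned to a gene.

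A table of splicing features covers 188 columns, of which 186 were used. The other 2 columns carry the muscle numbers 38 and 42, which no muscle sample is labelled with, and were not used here. The muscle libraries labelled 37 and 41 have no column under their own number; their count files carry 38 and 42, and they matched steers 38 and 42 best (correlation 0.593 and 0.688). The 2 columns may therefore be these 2 libraries, which was not established, so junctions cover 43 of the 45 muscle libraries. Its values are in another unit than counts, deposited by the authors without a statement of the unit; they look scaled by feature length and library size. Of its 1111674 lines, 364470 repeated an ID, and 202 IDs with differing values were dropped, which left 747002 features. Of these, 356171 were junctions. In each library all junction values above the floor of 0.775 were whole multiples of 1 step, within 0.001 of a step, so read numbers were recovered by dividing by the step and subtracting 1. This recovery is an inference from the values and not a stated unit.

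Steers carry the same number in each tissue. Rumen, liver and backfat had 48 libraries each and muscle had 45. Tissue, breed (Kinsella, Angus, Charolais) and feed efficiency (High, Low) gave 24 groups, of which 21 held 8 libraries and 3 held 7. Gene counts per library ranged from 5.68 to 30.2 M, except for rumen steer 19 (Angus Low) with 0.0059 M. That library stayed in the fits and was left out of all means and SDs of CPM (counts divided by the library total in megareads). The label of 1 steer gave no backfat thickness.

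Each tissue was fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr on the 6 groups, quasi-likelihood with robust = TRUE), with 1 mean per group. The filter left 13987 genes in rumen epithelium, 13709 in liver, 13400 in muscle and 14377 in backfat. Contrasts were High minus Low averaged over breeds, High minus Low in each breed, the breed by feed efficiency interaction, breed, and each pair of breeds. A slope per mm of backfat thickness came from a fit with that term added. Tests were two-sided and p was adjusted by Benjamini-Hochberg within each contrast, with 0.05 as the threshold. Where a number at an unadjusted p under 0.05 is given, chance alone would put a share of about 0.05 of those tested there. A log2 fold change is given with its SE. The tissues were compared in 1 fit of all libraries, and a gene counted as tissue-enriched at an adjusted p under 0.05 and a log2 fold change of at least 2 against each of the other 3 tissues.

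Junctions with a mean value of at least 5 were compared between High and Low with limma 3.58.1 on log2 of the value plus 1. Thickness and the number of junctions per library were compared by permutation tests of 100000 resamples, whose smallest possible p is 1e-05. A cassette exon was an exon flanked by 2 numbered neighbours with a junction that skips it. Its inclusion was the mean of both inclusion junctions as a percentage of that mean plus the skipping reads. Inclusion was compared with limma on log2 odds for exons with at least 10 reads in 80% of libraries. For differences between tissues, at least 20 percentage points were also required. The comparison of cassette exons was added after the data were seen. Its limits of 5 to 95% on mean inclusion were set after a run without them had called 1259 exons for breed in liver and 1492 in muscle.

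The tests, the thresholds, the rule for named genes and most alternatives were chosen before the data were examined. Under that rule the genes with the largest changes at a mean of at least 1 CPM are named, and for feed efficiency over all breeds only genes whose change had 1 sign in the 3 breeds. None of the gene IDs could be paired with a name (0 matched the reference table, which follows another assembly). The files give no names, so at most 2 IDs per direction are printed for each comparison and nothing is said of what those genes do. Genes of the interaction are not named. For the same reason the gene lists fixed beforehand, such as those of hepatocyte, adipocyte or muscle fibre genes, could not be run. The tissue-enriched sets of these same libraries were tested in their place with camera, fry and an estimated correlation (limma).

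Alternatives chosen beforehand were the animal as a block for tissue-enriched genes, RLE scaling, no filter on low counts, robust = FALSE, DESeq2 1.42.0, an additive model, thickness as a covariate, only the libraries of 1 breed, and other limits for junctions and enriched genes. Alternatives added after seeing the data were 3 percentages of unassigned records as covariates, a term for muscle libraries with liver reads, leaving out each Angus library in turn, leaving out libraries that matched another steer, the animal as a block for junctions and exons, edgeR on recovered junction reads, and no limits on inclusion. Labels were also permuted among steers, with 60 splits per tissue for genes, 100 for junctions and exons, and 24 for tissues, the real split included. Chance is called excluded only where no permuted split reached the real value, without correction for the number of such tests. Calling was tested on simulated data with 200 genes changed in each of the 4 tissues, among the genes tested there. The contrast of High and Low over all breeds recovered 74.6 to 83.6% of genes changed 1.5-fold and 100% of those changed 4-fold. The contrast within Angus recovered 35.8 to 53.7% and 92.4 to 98.5%. Counts were simulated independently for each gene, so these rates do not account for variation shared between genes, which the real libraries show. Each library was also compared with the other tissues of all steers over 200 genes, and 178 of 188 libraries matched their own steer best. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Counting error is the only error that the binomial intervals cover.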

Results

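The transcriptome of 4 tissues was measured by RNA sequencing in 48 beef steers of 3 breeds, named in the labels as Angus, Charolais and Kinsella, each with steers of High and of Low feed efficiency. Rumen epithelium, liver and backfat gave 48 libraries each and muscle gave 45, so that 189 libraries fell into 24 groups of tissue, breed and feed efficiency. There were 8 libraries in 21 of these groups and 7 in the other 3. Reads assigned to genes, in megareads (M), averaged 13.4 ± 3.73 M (SD, n = 48) in rumen epithelium, 18.0 ± 4.12 M (n = 48) in liver, 18.5 ± 5.86 M (n = 45) in muscle and 9.99 ± 1.65 M (n = 48) in backfat. The range was 8.92 to 27.9 M in liver, 5.68 to 30.2 M in muscle and 6.68 to 15.6 M in backfat. In rumen epithelium 1 library, steer 19 of Angus Low, held 5889 counts, and the other 47 held 8.48 to 26.4 M. The 10 most abundant genes took 40.7% of counts in muscle, 29.1% in liver, 23.6% in rumen epithelium and 18.7% in backfat. Of the 24616 genes, 809 had no count in any library. Gene IDs are given as in the files, which do not pair them with names.

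The tissues were compared first, to see which genes each expressed far above the others. Each tissue had genes that were almost private to it. In rumen epithelium, ENSBTAG00000004097 reached 17780 ± 4188 CPM (counts divided by the library total in M; SD, n = 47), against at most 1.13 CPM in the other tissues, and ENSBTAG00000012638 reached 9631 ± 3426 CPM. In liver, ENSBTAG00000017121 reached 85740 ± 15790 CPM (n = 48) and ENSBTAG00000007273 reached 30890 ± 3822 CPM. In muscle, ENSBTAG00000026986 reached 196200 ± 40830 CPM (n = 45) and ENSBTAG00000018204 reached 33960 ± 6904 CPM. The top backfat gene was less exclusive: ENSBTAG00000021466 reached 18850 ± 5952 CPM (n = 48) in backfat, but also 1573 ± 818 CPM in rumen epithelium and 916 ± 392 CPM in muscle. ENSBTAG00000015980 reached 18380 ± 5899 CPM in backfat and at most 152 CPM in the other tissues.

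Of 15290 genes tested with edgeR, 2964 were enriched in 1 tissue: 963 in liver, 769 in rumen epithelium, 660 in muscle and 572 in backfat. For the 8 genes named, the smallest log2 fold change against any other tissue was 3.03, for ENSBTAG00000021466 in backfat against muscle (adjusted p = 3.45e-61). The liver set took 53.7 ± 2.46% (SD, n = 48) of the counts of liver libraries, and the muscle set took 59.6 ± 2.80% (n = 45) of those of muscle. The rumen set took 19.8 ± 1.93% (n = 47) and the backfat set 18.1 ± 1.66% (n = 48) in their own tissues. Outside its own tissue no set averaged above 2.07% of counts, the value of the muscle set in backfat. Between any pair of tissues 88.4 to 90.2% of genes differed. With RLE in place of TMM scaling, the median log2 fold change of all genes moved by -0.34 for rumen epithelium minus liver, -0.39 minus muscle and -0.61 minus backfat, and by -0.28 and -0.22 for liver and muscle minus backfat, so directions are relative to these shifts. The sets were then 612 genes for rumen epithelium, 938 for liver, 660 for muscle and 809 for backfat.

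**Figure D1:**
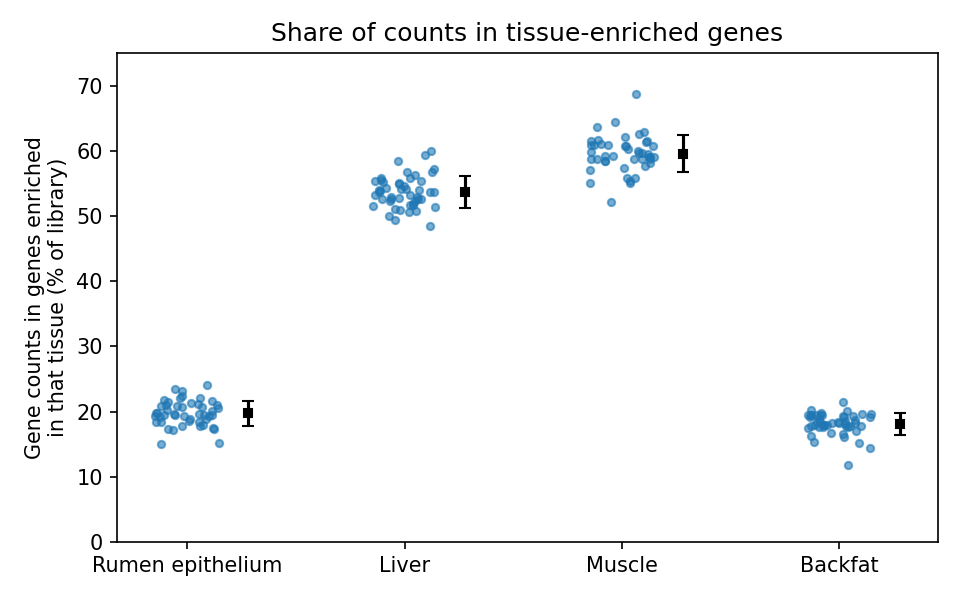
Percentage of each library's gene counts (y axis) that fell in the genes enriched in its own tissue, with 1 point per library and a black square and bar for the mean and 1 SD of each tissue (x axis). The liver and muscle sets averaged 53.7% and 59.6%, and the rumen and backfat sets 19.8% and 18.1%.

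Feed efficiency was compared next, High minus Low averaged over the 3 breeds. Few genes passed in any tissue, and most of them were in muscle, where 7 rose and 24 fell in High steers. In muscle, ENSBTAG00000047947 rose by 3.86 ± 0.88 (log2, SE; adjusted p = 0.0454), with 35.7 ± 84.0 CPM (SD, n = 23) in High and 2.58 ± 4.59 CPM (n = 22) in Low, and 16 of the 23 High libraries lay above the Low median; High steers 10 and 29 stood at 313.1 and 281 CPM. ENSBTAG00000002580 rose by 0.30 ± 0.066 (adjusted p = 0.0357), from 59.7 ± 18.9 to 73.9 ± 18.4 CPM, above the Low median in 20 of 23. ENSBTAG00000005260 changed by -2.53 ± 0.56 (adjusted p = 0.0454), with 1.17 ± 0.774 CPM in High and 9.86 ± 32.1 in Low, where steer 24 alone stood at 152.3 CPM, and ENSBTAG00000042190 by -1.33 ± 0.30 (adjusted p = 0.0454), with 0.755 ± 0.737 and 2.04 ± 1.67 CPM. Both lay below the Low median in 19 of 23 High libraries.

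In liver, edgeR called a single gene, ENSBTAG00000003601, which was chosen after its values were seen. It averaged 2.27 CPM and rose by 0.58 ± 0.11 (log2, SE; adjusted p = 0.0178). Its log2 fold change was 1.21 in Angus, 0.58 in Kinsella and -0.031 in Charolais. In rumen epithelium and backfat edgeR called 0 genes. At an unadjusted p under 0.05 there were 478 genes in rumen epithelium, 1185 in liver, 1537 in muscle and 1049 in backfat. DESeq2 called 0, 5, 106 and 14 in the same order, with all 5 of liver lower in High, and an additive model called 0 in each. Without a filter on low counts, muscle gave 7 genes, and with thickness as a covariate 14. With 2 alternatives chosen after seeing the data, muscle gave 11 genes (2 up, 9 down) with a term for the 11 muscle libraries that held liver reads, described below, and 55 (10 up, 45 down) with 3 percentages of unassigned records as covariates. Here and below, a muscle library is said to hold liver reads if the most abundant liver-enriched gene reached 1 CPM, whatever the source of its reads. None of the 4 muscle genes named passed without a filter or in the additive model. ENSBTAG00000047947 also missed the threshold with thickness or the term for liver reads, and ENSBTAG00000042190 with each of these and with the unassigned records.

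Within Angus the difference between High and Low was larger. In muscle of Angus steers 742 genes rose and 1037 fell in High. ENSBTAG00000017121, the most abundant liver-enriched gene, was at 10.6 ± 4.41 CPM (SD, n = 8) in Angus High muscle and at 0.016 ± 0.031 CPM (n = 8) in Angus Low, a log2 fold change of 8.47 ± 1.44 (SE; edgeR adjusted p = 0.000141), with 7 of 8 High libraries above the Low median. It stood at 1 CPM or more in 11 of the 45 muscle libraries, those of steers 5 and 26 to 35, and its highest level of 13.2 CPM was 0.0154% of its mean in liver. Genes of one tissue were also seen in libraries of others beside muscle. ENSBTAG00000017121 stood at 1 CPM or more in 37 of 48 backfat libraries, at up to 15.6 CPM. The muscle-enriched gene ENSBTAG00000026986 reached up to 432.5 CPM in rumen epithelium and 278 CPM in liver. ENSBTAG00000047947 rose by 6.80 ± 1.73 (adjusted p = 0.00707; 7 of 8), to 49.3 ± 95.8 CPM. ENSBTAG00000015340 changed by -5.01 ± 0.96 (adjusted p = 0.000512; 7 of 8), from 8.87 ± 20.9 CPM in Low to 0.29 ± 0.255 CPM in High, and ENSBTAG00000014969 by -4.45 ± 1.06 (adjusted p = 0.00397; 7 of 8), from 3.69 ± 5.81 to 0.181 ± 0.131 CPM. With a term for the 11 libraries that held liver reads, chosen after seeing the data, 114 genes passed in place of 1779 (30 up, 84 down). That term covers 7 of 8 Angus High libraries and 0 of 8 Angus Low. With it the median size of the log2 fold changes of the 1779 genes went from 0.502 to 0.435 and 1764 kept their sign, while the median SE rose from 0.135 to 0.186, so the lower count goes with a loss of precision and does not show that the change was removed. The share of records with more than 1 alignment was 37.1 ± 6.79% (n = 8) in Angus High and 44.3 ± 5.98% (n = 8) in Angus Low muscle. A fit with 3 percentages of unassigned records gave 898 genes, and a fit of the Angus libraries alone gave 1112.

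**Figure D2:**
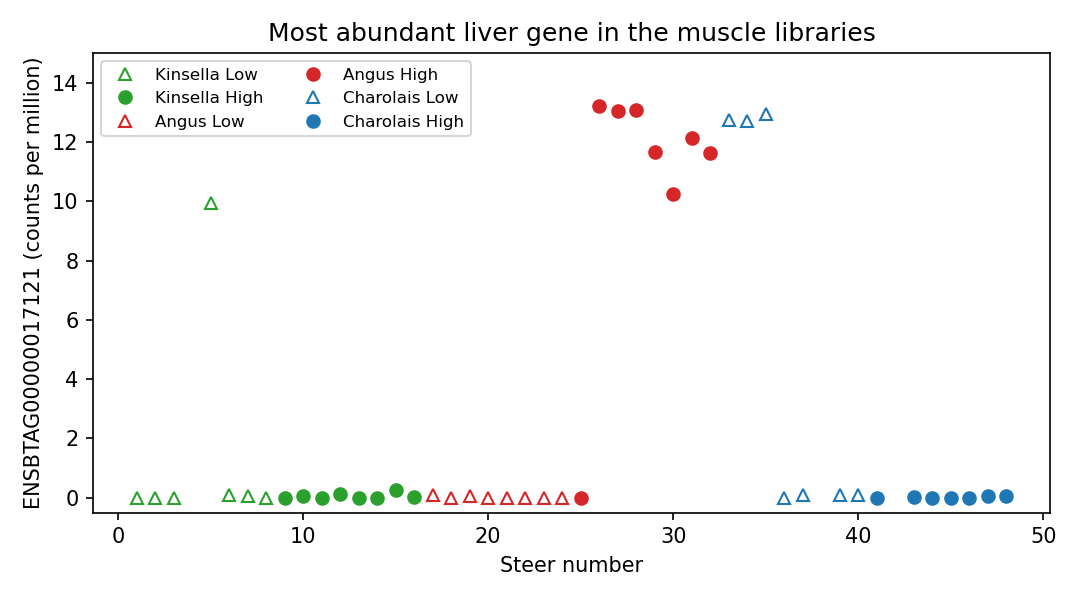
CPM of the liver-enriched gene ENSBTAG00000017121 in muscle libraries (y axis) by steer number (x axis), with colours for breed, open triangles for Low and filled circles for High. The 11 libraries at 1 CPM or more are those of steers 5 and 26 to 35.

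In liver of Angus steers 261 genes rose and 177 fell in High. ENSBTAG00000019770 rose by 3.13 ± 0.60 (log2, SE; edgeR adjusted p = 0.00303), from 46.5 ± 45.1 CPM (SD, n = 8) in Low to 423 ± 444 CPM (n = 8) in High, and ENSBTAG00000039673 by 2.08 ± 0.50 (adjusted p = 0.0148), from 0.476 ± 0.519 to 2.09 ± 1.71 CPM. All 8 High libraries lay above the Low median for both. ENSBTAG00000015052 changed by -2.09 ± 0.62 (adjusted p = 0.049; 7 of 8), with 0.949 ± 0.856 CPM in High and 4.13 ± 5.95 in Low, and ENSBTAG00000047957 by -2.04 ± 0.53 (adjusted p = 0.026; 8 of 8), with 4.64 ± 2.24 and 19.5 ± 15.7 CPM. ENSBTAG00000015052 no longer passed without any one of Low steers 17 to 21 and 23 and High steers 25 to 29 and 32, at log2 fold changes of -1.15 (without steer 23) to -2.25, and ENSBTAG00000047957 without Low steer 19 or 21 or High steer 28 or 30 (-1.71 to -1.95). Single libraries moved the count of 438 over 1.5 times: it was 197 without Low steer 17, 201 without 19, 244 without 20 and 257 without 21. It was 208 without High steer 25, 275 without 28, 231 without 30, 1416 without 31 and 239 without 32. Other settings that moved it were no filter on low counts (226), DESeq2 (667) and the Angus libraries alone (91).

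In rumen epithelium of Angus steers 97 genes rose and 157 fell in High. ENSBTAG00000014069 rose by 1.48 ± 0.37 (log2, SE; edgeR adjusted p = 0.0366; 7 of 8), from 27.1 ± 12.6 CPM (SD, n = 7) in Low to 82.7 ± 61.0 CPM (n = 8) in High, and ENSBTAG00000015875 by 1.45 ± 0.37 (adjusted p = 0.0391; 8 of 8), from 0.758 ± 0.593 to 2.20 ± 1.19 CPM. ENSBTAG00000047431 changed by -1.96 ± 0.40 (adjusted p = 0.0239; 8 of 8), with 0.525 ± 0.133 CPM in High and 1.91 ± 1.17 in Low, and ENSBTAG00000030306 by -1.76 ± 0.43 (adjusted p = 0.0349; 8 of 8), with 3.96 ± 2.51 and 12.6 ± 8.05 CPM. Each of these 4 genes lost its call without Low steer 17, 20 or 21 or High steer 26. ENSBTAG00000014069 also lost it without steer 24, 27 or 30, ENSBTAG00000015875 without steer 24, 27, 30 or 31 and ENSBTAG00000030306 without steer 24, 27, 31 or 32. Their log2 fold changes over all fits without 1 library were 1.14 to 1.63, 1.24 to 1.76 and -2.09 to -1.48, and -2.10 to -1.65 for ENSBTAG00000047431. The share of records outside genes was 27.4 ± 6.19% (SD, n = 8) in Angus High and 19.1 ± 7.27% (n = 7) in Angus Low. Across genes, the change of Angus rumen epithelium had a rank correlation of 0.326 with the number of exon regions of the gene, the largest of 16 such values for the breed pairs and Angus over the tissues, and a correlation of 0.571 in size with the first axis of variation within groups of rumen libraries, which held 23.1% of the variance within groups. The count of 254 rested on single libraries: it was 0 without Low steer 17, 20 or 21 and without High steer 26. It was 104 without Low steer 18, 421 without 19, 455 without 22, 1731 without 23 and 59 without 24, and 114 without High steer 27, 37 without 30, 78 without 31 and 78 without 32. DESeq2 gave 407 genes (228 up, 179 down), RLE scaling 75 (35 up, 40 down), no filter 42 (9 up, 33 down), the Angus libraries alone 584, and covariates of unassigned records 0.

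In backfat of Angus steers edgeR called 5 genes, all lower in High. ENSBTAG00000047540 changed by -2.29 ± 0.44 (log2, SE; adjusted p = 0.0239), with 0.281 ± 0.232 CPM (SD, n = 8) in High and 1.30 ± 0.842 (n = 8) in Low. ENSBTAG00000014506 changed by -0.88 ± 0.18 (adjusted p = 0.03), with 18.5 ± 4.32 and 32.3 ± 11.0 CPM. All 8 High libraries lay below the Low median for both. ENSBTAG00000047540 no longer passed without Low steer 21 or 22 or High steer 26, 27, 28, 29, 31 or 32 (-2.06 to -2.33), and ENSBTAG00000014506 without Low steer 17, 18, 21, 22 or 23 or High steer 27, 28, 29, 31 or 32 (-0.80 to -0.89). At an unadjusted p under 0.05 there were 1759 genes. DESeq2 called 79 (9 up, 70 down), and the Angus libraries alone and the covariates of unassigned records each gave 1. The count of 5 was 1 without Low steer 21 and without High steer 27, 28, 29 or 31. It was 3 without Low steer 17, 27 without 19, 2 without 22, 2 without 23 and 8 without 24, and it was 117 without High steer 25, 3 without 26 and 2 without 32.

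In Charolais the comparison of High with Low called 13 genes in muscle, 1 up and 12 down. ENSBTAG00000013198 rose by 1.32 ± 0.26 (log2, SE; edgeR adjusted p = 0.0293; 6 of 7), from 1.72 ± 0.32 CPM (SD, n = 7) in Low to 4.31 ± 3.07 CPM (n = 7) in High. The liver-enriched gene ENSBTAG00000017121 changed by -7.76 ± 1.5 (adjusted p = 0.0293; 7 of 7), with 0.02 ± 0.025 CPM in High and 5.53 ± 6.81 CPM in Low, where 3 of 7 libraries held liver reads. ENSBTAG00000004526 changed by -3.76 ± 0.79 (adjusted p = 0.0293; 5 of 7), with 2.08 ± 1.19 and 26.9 ± 66.2 CPM, but the Low mean rests on steer 34 at 177 CPM, and the other 6 Low libraries lay at 1.007 to 3.1 CPM. The count was 0 with the term for liver reads, with covariates of unassigned records and in the Charolais libraries alone, 8 without a filter and 4 with DESeq2. In the other 3 tissues of Charolais, edgeR called 0 genes, with 753, 1154 and 562 genes in rumen epithelium, liver and backfat at an unadjusted p under 0.05, and DESeq2 called 0, 6 and 1. In Kinsella, edgeR called 0 genes in all 4 tissues, with 3184, 917, 836 and 1361 genes in rumen epithelium, liver, muscle and backfat at an unadjusted p under 0.05, and DESeq2 called 0, 0, 6 and 3.

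Whether the breeds differed in their response was tested by the interaction. In rumen epithelium 890 genes passed (edgeR), in liver 263, in muscle 462 and in backfat 0. Backfat had 1467 genes at an unadjusted p under 0.05, and DESeq2 called 28 there. DESeq2 called 1093, 478 and 797 in rumen epithelium, liver and muscle. The rumen count was 464 with RLE scaling, 65 without a filter and 0 with covariates of unassigned records. The liver count was 147 without a filter and 26 with those covariates. The muscle count was 155 with them and 0 with the term for liver reads. Of the genes called in Angus, liver and muscle shared 56, against 54 for independent lists, rumen epithelium and liver 7 (7.79), rumen epithelium and muscle 18 (32.3) and muscle and backfat 3 (0.409). Backfat shared 0 with rumen epithelium (0.059) and 0 with liver (0.0986).

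The 3 breeds were then compared in each tissue, averaged over feed efficiency. Breed separated more genes than feed efficiency did in each tissue, with 7718 genes in liver, 7143 in muscle, 3491 in backfat and 2885 in rumen epithelium (edgeR F test). A single gene, ENSBTAG00000016063, was among the largest declines in Charolais in all 4 tissues. It stood at 0.137 ± 0.116 CPM (SD, n = 16) in Charolais rumen epithelium against 3.33 ± 3.33 (n = 15) in Angus, a log2 fold change of -4.49 ± 0.78 (SE; adjusted p = 0.000166; below the Angus median in 16 of 16). In liver it stood at 0.185 ± 0.129 against 2.58 ± 2.74 CPM in Angus (-3.92 ± 0.68; adjusted p = 1e-05; 16 of 16). Against Kinsella it was at 0.052 ± 0.076 and 4.60 ± 5.2 CPM in muscle (-6.24 ± 1.22; adjusted p = 6.46e-05; 14 of 14), and at 0.192 ± 0.217 and 3.49 ± 3.93 CPM in backfat (-4.03 ± 0.84; adjusted p = 0.000601; 16 of 16).

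Liver of Angus steers differed most from the other breeds, in 6749 genes from Kinsella and 6758 from Charolais, whereas Charolais and Kinsella differed in 479. Angus minus Kinsella gave 3193 genes up and 3556 down, and Charolais minus Angus gave 3462 up and 3296 down. ENSBTAG00000002705 was at 9.46 ± 14.5 CPM (SD, n = 16) in Charolais and at 0.209 ± 0.133 (n = 16) in Angus (log2 5.43 ± 1.1, SE; edgeR adjusted p = 9.14e-05; 12 of 16), and ENSBTAG00000046695 rose by 5.57 ± 1.73 (adjusted p = 0.00703; 9 of 16), to 2.02 ± 4.18 CPM. ENSBTAG00000016712 changed by -2.88 ± 0.58 (adjusted p = 7.65e-05; 16 of 16), from 14.9 ± 12.8 CPM in Angus to 2.32 ± 2.50. The share of records with more than 1 alignment moved with breed in liver, at 33.6 ± 7.12% (n = 16) in Angus, 44 ± 6.10% in Charolais and 64.6 ± 17.6% in Kinsella. With 3 percentages of unassigned records as covariates, chosen after seeing the data, Angus minus Kinsella gave 3 genes. Charolais minus Kinsella gave 30 and Charolais minus Angus 3141. Over the genes called without these covariates, the median size was then 0.246 for Angus minus Kinsella and 0.294 for Charolais minus Angus. The median SE was 0.165 and 0.116 in the same order. The 3 genes thus go partly with a loss of precision and do not show that Angus and Kinsella were alike.

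In muscle it was Charolais that stood apart, with 5970 genes against Kinsella (2881 up, 3089 down) and 5156 against Angus (2427 up, 2729 down). Angus minus Kinsella gave 903 up and 1215 down. Against Kinsella, ENSBTAG00000012710 rose by 3.97 ± 1.40 (log2, SE; edgeR adjusted p = 0.0191; above the Kinsella median in 7 of 14), with 3.61 ± 3.94 CPM (SD, n = 14) and 1.27 ± 2.25 (n = 15). ENSBTAG00000039035 rose by 2.68 ± 0.93 (adjusted p = 0.0179; 10 of 14), with 18.6 ± 27 and 3.72 ± 6.90 CPM. ENSBTAG00000048205 changed by -5.44 ± 1.77 (adjusted p = 0.0115), with 1.49 ± 5.57 and 8.04 ± 15.2 CPM, but 0 of 14 Charolais libraries lay below the Kinsella median. The share of records with more than 1 alignment was 36 ± 2.80% in Charolais, 40.7 ± 7.21% in Angus and 46 ± 6.84% in Kinsella. With the covariates of unassigned records the order of the counts turned. They were 1355 for Charolais minus Kinsella, 1783 for Angus minus Kinsella and 2349 for Charolais minus Angus. Over the 5970 genes called before between Charolais and Kinsella, the median size of the log2 fold change went from 0.414 to 0.261 and 5649 kept their sign. The median SE rose from 0.0978 to 0.138, so the lower count goes partly with a loss of precision and does not rank the pairs by closeness. With the term for liver reads Angus minus Kinsella gave 1115, Charolais minus Kinsella 6033 and Charolais minus Angus 4407.

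In backfat and rumen epithelium fewer genes differed. In backfat Kinsella stood apart, with 1937 genes against Angus (898 up and 1039 down in Angus) and 2786 against Charolais (1263 up and 1523 down in Charolais), while Charolais minus Angus gave 717. ENSBTAG00000011985 rose by 4.71 ± 0.79 in Charolais over Kinsella (log2, SE; edgeR adjusted p = 3.73e-05; 11 of 16), from 0.261 ± 0.215 to 7.02 ± 9.00 CPM (SD, n = 16 each), and ENSBTAG00000023032 by 2.54 ± 0.55 (adjusted p = 0.000864; 11 of 16), from 0.461 ± 0.558 to 2.70 ± 3.57 CPM. ENSBTAG00000047540, lower in High than in Low Angus backfat, was also lower in Charolais than in Kinsella, at 0.179 ± 0.17 against 2.03 ± 0.748 CPM (-3.54 ± 0.33; adjusted p = 3.57e-10; 16 of 16). With the covariates of unassigned records Angus minus Kinsella gave 1171 genes in backfat, Charolais minus Kinsella 2797 and Charolais minus Angus 604.

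In rumen epithelium Charolais minus Angus gave the most genes, 1658 up and 934 down. ENSBTAG00000045747 rose by 6.51 ± 0.87 (log2, SE; edgeR adjusted p = 4.64e-06; 11 of 16), to 3.03 ± 2.37 CPM (SD, n = 16) from 0.028 CPM (n = 15), and ENSBTAG00000047918 by 7.00 ± 1.66 (adjusted p = 0.0035; 11 of 16), to 6.4 ± 13.6 from 0.079 CPM. ENSBTAG00000006231 changed by -3.55 ± 0.75 (adjusted p = 0.00095; 14 of 16), from 3.13 ± 3.91 to 0.247 CPM. Angus minus Kinsella gave 241 up and 797 down, and Charolais minus Kinsella 252 up and 348 down. RLE scaling moved the balance of directions, to 1975 up and 487 down for Charolais minus Angus and to 125 up and 1166 down for Angus minus Kinsella. Without a filter Angus minus Kinsella gave 641 genes. The covariates of unassigned records gave 53 for Angus minus Kinsella, 291 for Charolais minus Kinsella and 2824 for Charolais minus Angus.

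The breed differences were compared across tissues over the 12053 genes tested in all 4. Of these, 537 were called for breed in every tissue, against 191 for independent lists. Among the 537 genes, Angus minus Kinsella had 1 sign in all 4 tissues for 421, Charolais minus Kinsella for 70 and Charolais minus Angus for 32. The 4 tissues come from the same steers, so their signs are not independent, and agreement between tissues is not by itself evidence of a breed effect. Rumen epithelium and liver moved together: of 1810 genes called for Charolais minus Angus in both, 98.9% changed in the same direction, with a correlation of log2 fold changes across genes of 0.71. Liver and muscle moved in opposite directions for that pair: of 2808 genes called in both, 12.9% changed in the same direction (r across genes = -0.35), and in rumen epithelium and muscle 12.1% of 995 did. For Angus minus Kinsella, 98.8% of 655 genes agreed in direction between rumen epithelium and liver, and 77.2% of 1100 between liver and muscle. For Charolais minus Kinsella, 88.2% of 1383 genes agreed between muscle and backfat, but 41.8% of 177 between liver and muscle. Genes are not independent replicates, so these correlations carry no p. With breed labels permuted among steers, 11 of 60 splits reached in size that of rumen epithelium and muscle for Charolais minus Angus (-0.22). For liver and muscle, 3 of 60 reached that of Angus minus Kinsella (0.30) and 38 of 60 that of Charolais minus Kinsella (0.099). Chance stays open for these. At most 2 of 60 did so for the other pairs of tissues named here.

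**Figure D3:**
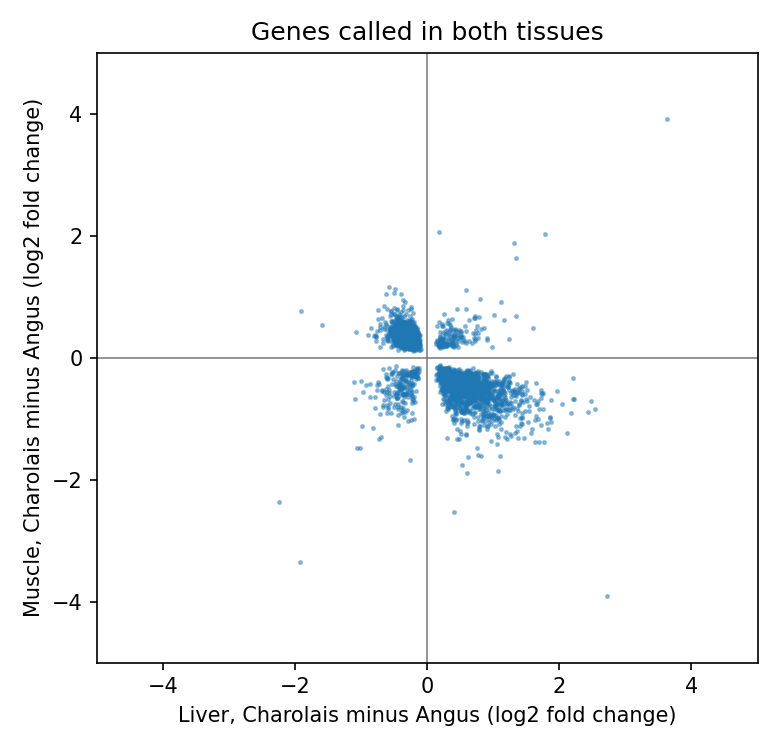
Log2 fold change of Charolais minus Angus in liver (x axis) and in muscle (y axis), with 1 dot for each of 2844 genes called in both tissues. Of these genes 373 changed in the same direction in both tissues, and 1 lies outside the axes.

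Shifts of whole tissue-enriched sets between breeds were tested next. These sets were chosen on the same libraries, so they are not independent evidence of direction. In muscle, genes of the backfat set were lower in Charolais: 175 of 385 fell and 6 rose against Kinsella (median log2 -0.42; camera adjusted p = 4.23e-11), and 209 fell and 1 rose against Angus (median -0.50; adjusted p = 2.72e-18). With an estimated correlation the adjusted p values were 0.49 and 0.187, and fry gave adjusted p values of 3.13e-05 and 1.43e-05. The muscle set itself was higher in Charolais than in Angus muscle, with 202 of 660 genes up and 44 down (camera adjusted p = 3.95e-07; adjusted p = 0.242 with an estimated correlation). In liver, the backfat set was lower in Angus: 129 of 276 genes fell and 10 rose against Kinsella (median -0.37; adjusted p = 6.18e-07, and 0.234 with an estimated correlation). Charolais minus Angus gave 129 up and 14 down in the same set (median 0.37; adjusted p = 1.16e-06, and 0.425 with an estimated correlation). The liver set in Angus minus Kinsella liver had 318 of 963 genes up and 152 down (adjusted p = 0.00307, and 0.234 with an estimated correlation). The directions held under RLE scaling.

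Backfat thickness, given in the labels for 47 steers, averaged 10.6 ± 2.75 mm (SD). It was 10.5 ± 2.60 mm in 24 High steers and 10.6 ± 2.96 mm in 23 Low steers, a difference of -0.107 mm (permutation p = 0.897, labels permuted within breed). The breeds differed, with 11.3 ± 2.49 mm in Kinsella (n = 15), 11.2 ± 2.94 mm in Angus (n = 16) and 9.15 ± 2.36 mm in Charolais (n = 16; F = 3.54, permutation p = 0.0373). The slope of expression on thickness passed for 0 genes in each tissue with edgeR, with 839, 601, 1594 and 825 genes in rumen epithelium, liver, muscle and backfat at an unadjusted p under 0.05. DESeq2 called 0, 0, 20 and 2, and edgeR without a filter called 1 in muscle. As a set, the rumen-enriched genes decreased with thickness in muscle (280 genes, median slope -0.019 per mm; camera adjusted p = 1.09e-06). That call held with an estimated correlation (adjusted p = 0.0136) and fry gave an adjusted p of 0.00285. Without the 2 muscle libraries that matched another steer (n = 42), chosen after seeing the data, the adjusted p was 4.34e-06 (median slope -0.021), 0.0268 with an estimated correlation and 0.00552 with fry. The muscle set increased with thickness in muscle (660 genes, median 0.014 per mm; adjusted p = 6.78e-09, 0.0871 with an estimated correlation and 0.0339 with fry), and without those 2 libraries the values were 1.59e-08, 0.0885 and 0.0484. The liver set and the backfat set decreased as well (475 and 389 genes, median slopes -0.0113 and -0.0128; camera adjusted p = 0.000393 for both, 0.0871 and 0.405 with an estimated correlation, 0.0339 and 0.35 with fry), and without those 2 libraries (medians -0.0121 and -0.0135) camera gave 0.000724 for both, an estimated correlation 0.0885 and 0.419, and fry 0.0484 and 0.342. By camera all 3 sets of other tissues decreased and the muscle set increased, but with an estimated correlation only the rumen set passed, so whether the shift was particular to rumen genes stays open. No single gene of these 4 sets passed on its own in that edgeR fit.

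Splice junctions were counted in each library to see how splicing differed between tissues. Backfat showed the most junctions with a value of at least 1, 148990 ± 6461 (SD, n = 48), followed by rumen epithelium with 141350 ± 7670 (n = 47), liver with 140110 ± 5658 (n = 48) and muscle with 128670 ± 11890 (n = 43). The tissues differed (F = 47.54, permutation p = 1e-05, the smallest these permutations can give), also with all libraries thinned to 5054933 junction reads (F = 263.8). Backfat had the fewest junction reads, 8.01 ± 1.56 M, and muscle the most, 19.2 ± 6.92 M. Junctions that joined a pair of genes took 12.3 ± 1.41% of junction reads in muscle, 8.50 ± 0.887% in rumen epithelium, 2.79 ± 0.35% in liver and 0.484 ± 0.19% in backfat. Introns with a value of at least 1 numbered 15224 ± 1324 in backfat and 4307 ± 336 in muscle. Intron numbers were not thinned to an equal depth, so depth and tissue cannot be told apart in them. Per the labels, backfat RNA came from another kit than that of the other tissues. In any comparison of backfat with another tissue, kit and tissue cannot be told apart.

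Feed efficiency moved few junctions. In muscle 11 junctions of 93544 tested fell in High steers (limma), the first of them between exons 1 and 2 of ENSBTAG00000008314 (-0.89 ± 0.13, log2, SE; adjusted p = 0.0015). In backfat 1 of 133600 fell, between exons 1 and 2 of ENSBTAG00000046014 (-1.14 ± 0.19; adjusted p = 0.0393), chosen after its values were seen. In rumen epithelium and liver limma called 0 of 116417 and 0 of 103324. At an unadjusted p under 0.05 there were 5850, 8310, 8732 and 6992 junctions in rumen epithelium, liver, muscle and backfat. Those of rumen epithelium and backfat are close to the share of 0.05 that chance alone gives. With edgeR on recovered reads the counts were 0, 0, 5 (1 up, 4 down) and 0, and with a lower limit of 1 on the mean value muscle gave 5 and backfat 0.

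Cassette exons, which a transcript can include or skip, separated muscle from the other tissues. Exon 3 of ENSBTAG00000012890 had an inclusion of 93.6 ± 3.33% (SD, n = 43) in muscle but of 1.02% (n = 47) in rumen epithelium, 0.916% (n = 48) in liver and 0.705% (n = 48) in backfat. Exon 97 of ENSBTAG00000021237 was included in 90.7 ± 5.53% in muscle and in at most 3.67% elsewhere. Conversely, exon 6 of ENSBTAG00000011424 was included in 2.06 ± 0.833% in muscle and in at least 93.0% elsewhere, and exon 13 of ENSBTAG00000015839 in 18.2 ± 5.44% in muscle and in at least 90.9% elsewhere. In rumen epithelium, exon 12 of ENSBTAG00000004636 was included in 7.25 ± 3.19%, against 66.9% in liver, 89% in muscle and 95.6% in backfat. In backfat, exon 6 of ENSBTAG00000000874 was included in 67.2 ± 6.93% and in at most 11.9% elsewhere, and exon 6 of ENSBTAG00000025443 in 5.44 ± 4.54% against at least 61.6% elsewhere.

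Of 1039 exons tested in all tissues, 221 differed by at least 20 percentage points in some pair of tissues (limma). Muscle was apart from each of the others in 76 exons, 38 included more and 38 less, rumen epithelium in 25, liver in 16 and backfat in 11. The pair of rumen epithelium and muscle gave the most, 151 exons, and the pair of rumen epithelium and liver the fewest, 50. Between breeds, 13 exons differed in liver, 10 in muscle, 8 in backfat and 0 in rumen epithelium, where 112 had an unadjusted p under 0.05. Between High and Low averaged over breeds limma called 0 exons in each tissue, with 54, 48, 46 and 66 in rumen epithelium, liver, muscle and backfat at an unadjusted p under 0.05. Within breeds it called 2 in Angus rumen epithelium, 2 in Angus muscle, 1 in Kinsella liver and 1 in Kinsella muscle, and the interaction gave 1 in rumen epithelium. The other contrasts within breeds gave 0, with 32 to 81 exons at an unadjusted p under 0.05, and the interaction gave 0 in liver, muscle and backfat, with 59, 62 and 80. Without limits on mean inclusion, breed gave 9 exons in rumen epithelium, 1259 in liver, 1492 in muscle and 103 in backfat.

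**Figure D4:**
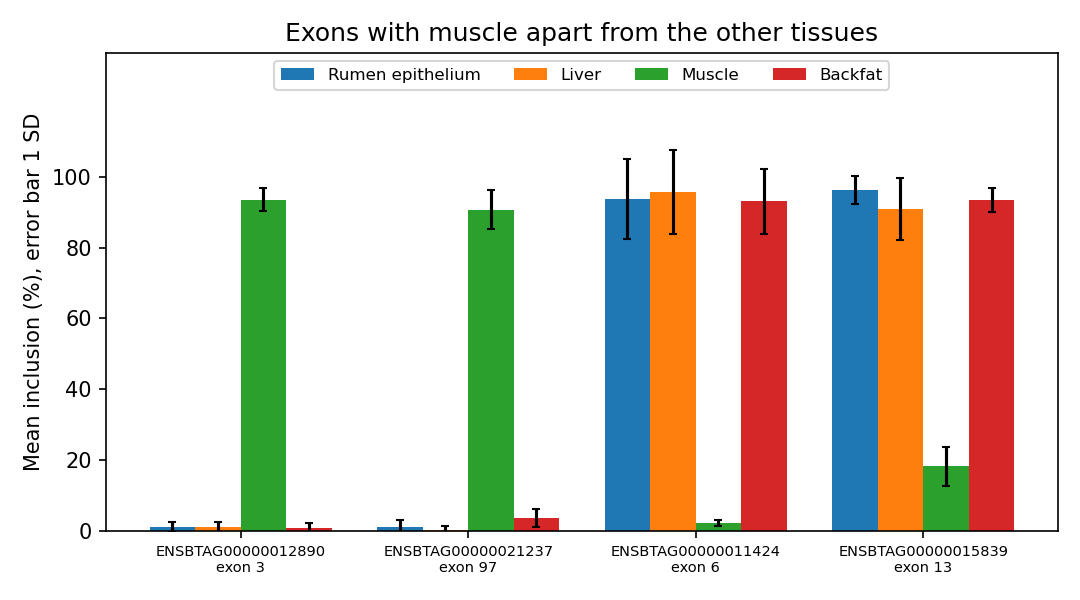
Inclusion of 4 cassette exons (y axis, %) in each tissue, with bars for the mean and error bars for 1 SD over 47 rumen, 48 liver, 43 muscle and 48 backfat libraries. Exon 3 of ENSBTAG00000012890 averaged 93.6% in muscle, and exon 6 of ENSBTAG00000011424 averaged 2.06% there.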

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

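Of the tests given here, those with unassigned records as covariates, that with the term for muscle libraries with liver reads, those of the match between library and steer, those of the axes and exon regions for feed efficiency in Angus, those of the axis of the same tissue for breed and all those with permuted labels were chosen only after the results were seen; the levels of 2 liver genes in muscle had also been seen before the other 19 were tested.

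Within groups of 7 or 8 libraries, 21 values stood apart from the rest of their group among 112 groups of values tested, where chance alone sets about 1 in 20 groups apart. In gene counts, rumen steer 19 (Angus Low) held 0.0059 M against 10.4 to 18.4 M in the others, liver steer 1 (Kinsella Low) 27.9 M against 8.92 to 13.8, muscle steer 25 (Angus High) 5.68 M against 15.2 to 22.9, and backfat steer 27 (Angus High) 15.6 M against 8.92 to 11.6. The share of counts in genes enriched in the own tissue was 50.57% in liver steer 10 (Kinsella High; others 52.5 to 54.1%), 49.32% in liver steer 31 (Angus High; others 55.3 to 59.4%) and 14.44% in backfat steer 19 (Angus Low; others 17.8 to 20.1%). The 95% Wilson intervals of these shares, which cover counting error only, were 50.55 to 50.59%, 49.29 to 49.34% and 14.41 to 14.46%. The number of junctions was 100877 in muscle steer 3 (Kinsella Low; others 119355 to 132851) and 88637 in muscle steer 25 (Angus High; others 128357 to 142251), the library with few counts.

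Among the genes named for feed efficiency in Angus, ENSBTAG00000014069 stood at 218.2 CPM in rumen steer 27 (High; others at most 103.9), ENSBTAG00000019770 at 1417 CPM in liver steer 31 (High; others at most 639.7), and ENSBTAG00000015052 at 17.9 CPM in liver steer 23 (Low; others at most 6.27). In muscle, ENSBTAG00000047947 stood at 281 CPM in steer 29 (High; others at most 50.6) and at 4.721 CPM in steer 21 (Low; others at most 0.219). ENSBTAG00000015340 stood at 60.33 CPM in muscle steer 20 (Low; others at most 7.33), and ENSBTAG00000014969 at 0.4855 CPM in steer 27 (High; others at most 0.19) and at 16.55 CPM in steer 20 (Low; others at most 6.89). ENSBTAG00000017121 stood at 0 CPM in muscle steer 25 (High; others 10.3 to 13.2). In backfat, ENSBTAG00000047540 stood at 0.7844 CPM in steer 25 (High; others at most 0.343). For feed efficiency in Charolais muscle, ENSBTAG00000004526 stood at 4.673 CPM in steer 47 (High; others at most 2.17) and at 177 CPM in steer 34 (Low; others at most 3.1).

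The effect of feed efficiency differed between breeds in 890 genes of rumen epithelium, 263 of liver and 462 of muscle by the interaction test. Of 60 splits of the steers, 2 gave as many in rumen epithelium (the other with 1012), 1 in liver (highest other 34) and 1 in muscle (highest other 1). Chance can therefore be excluded in liver and muscle and stays open in rumen epithelium. In rumen epithelium a split with more genes than the real one points to a structure of the libraries beside feed efficiency. The change within Angus there correlated at 0.571 with the first axis within groups of rumen libraries and at 0.326 by rank with the number of exon regions, so a structure of these libraries that goes with transcript size, which may be RNA quality or handling, remains a candidate explanation of it; with the axes of the other tissues the correlation was at most 0.104, which leaves an axis shared between tissues open. Feed efficiency stays open as a biological difference.

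The breed differences in liver and muscle are large, and for Charolais minus Angus they run in opposite directions. Chance can be excluded for their number (1 of 60 splits gave 7718 genes in liver, highest other 1491, and 1 of 60 gave 7143 in muscle, highest other 2) and for the opposite directions (correlation across genes -0.353, 1 of 60 splits, highest other 0.302). The number of exon regions of a gene does not account for the liver change of Charolais minus Angus (rank correlation across genes 0.057), and its correlation of -0.136 in muscle leaves that open. A shared axis of variation between libraries, which may be RNA quality, handling, the mix of cells or the state of the animals, remains a candidate explanation: the liver change correlated at 0.366 with the first axis within groups of backfat, and the muscle change at 0.405 with that of liver. With the axis of the same tissue the liver change correlated at 0.599, and the muscle change at 0.29, which leaves that axis open in muscle. With unassigned records as covariates the median ratio of new to old log2 fold change was 0.611 for Angus minus Kinsella and 0.717 for Charolais minus Angus in liver and 0.632 for Charolais minus Kinsella in muscle, between loss and persistence. In the last 2 of these 3040 of 6758 and 1293 of 5970 genes still passed (median size 0.4 to 0.294 and 0.414 to 0.261, median SE 0.1 to 0.116 and 0.0978 to 0.138), which argues against those shares as the whole cause and leaves a part open. In the first the median size went from 0.399 to 0.246 while the median SE rose from 0.1 to 0.165, so that 3 of 6749 genes still passed, and these shares and breed cannot be told apart there. Breed itself stays open as a biological difference.

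In Angus muscle the feed efficiency difference runs with reads of liver genes. Chance can be excluded (1 of 60 splits gave 1779 genes, highest other 162). Liver RNA or reads in muscle libraries fit as a candidate source of ENSBTAG00000017121 there: over the next 19 liver genes the median slope on it, scaled to liver levels, was 1.28, where 1 is expected of liver material, and the highest level was 0.0154% of that in liver. Beyond that gene, the 11 libraries may mark a batch that covers 7 of 8 Angus High and 0 of 8 Angus Low libraries: with that term the median ratio of log2 fold changes was 0.883 (quartiles 0.69 to 1.08), the median size went from 0.502 to 0.435 while the median SE rose from 0.135 to 0.186, 1764 of 1779 genes kept their sign and 108 still passed. Since the term nearly divides the 2 Angus groups and the quartiles reach from below to above 0.75, the bound set for a batch that is not the cause, that batch and feed efficiency cannot be told apart for these genes. With unassigned records the ratio was 0.836 (quartiles 0.741 to 0.933), all 1779 genes kept their sign, the median size went from 0.502 to 0.423 at a median SE of 0.135 before and after, and 841 genes still passed, which argues against those shares as the whole cause; a part stays open. The number of exon regions does not account for the change (rank correlation 0.0349). A shared axis of variation between libraries remains a candidate explanation here too, since the change correlated at 0.456 with the first axis within groups of liver; its correlation of 0.189 with that of muscle itself leaves the axis of muscle open.

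A few libraries matched another steer than the one they are labelled with, which suggests mislabelled samples. Muscle library 37 matched steer 38 (correlation 0.593, own 0.016) and muscle library 41 matched steer 42 (0.688, own 0.044). Rumen libraries 10 and 16 matched each other's steer (0.537 and 0.311, own -0.166 and 0.01), as did backfat libraries 27 and 31 (0.691 and 0.716, own 0.116 and -0.02). A further 4 libraries matched best a steer of another group of breed or feed efficiency: rumen 7 matched steer 28 (0.347, own 0.236), rumen 44 steer 6 (0.385, own 0.371), liver 10 steer 6 (0.36, own 0.277) and backfat 41 steer 26 (0.404, own 0.337). The profile of a steer was taken from its libraries of the other tissues as labelled. For liver 10 it includes rumen library 10, and for backfat 41 it includes muscle library 41, which both matched another steer. A low own match of liver 10 or backfat 41 is therefore not by itself a sign of a wrong label. Whether these 4 libraries are mislabelled stays open, and comparisons of groups were not run without them. Each of the 4 pairs named first lies within 1 group of breed and feed efficiency, so a wrong label there does not affect comparisons of groups within a tissue. It does affect values that join tissues by steer and the slopes on thickness; without the 6 libraries of those pairs edgeR still called 0 genes for the slope in rumen epithelium, muscle and backfat, and the rumen-enriched set still decreased with thickness in muscle (camera adjusted p = 4.34e-06, and 0.0268 with an estimated correlation). No biological explanation was tested for these.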

How the results depend on the processing

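The alternatives with unassigned records, the term for liver reads, single libraries left out, libraries that match another steer left out, edgeR on junction reads, the block for junctions and exons and no limits on inclusion were chosen only after the results were seen. Under an alternative there were 280 values of 61 summary results. Of these, 201 stayed on their side of the threshold or within 1.5 times, and 79 did not. A count of 0 that stayed at 0 is among the 201. Fits with 1 library left out are not among the 280. For feed efficiency in Angus there were 16 such fits per tissue. The count moved over 1.5 times in 13 of rumen epithelium, 9 of liver, 0 of muscle and 13 of backfat. Where no cause is named, the cause was not tested. Of 440 alternatives for 37 named genes, 334 still passed, 106 did not pass and 0 reversed. These 440 leave out each case where the alternative filtered the gene out or gave it no adjusted p. With DESeq2, 30 named genes passed and 1 did not, and the rest of the 37 are not counted. With only the libraries of 1 breed, 4 passed and 6 did not, and the other genes named within a breed are not counted. The gene lists fixed beforehand were not run, since no ID could be paired with a name.

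Fewer genes meet a log2 limit of 3 by construction: 1771 tissue-enriched genes, with 491 in rumen epithelium, 429 in muscle and 181 in backfat. With no filter, backfat gave 907 enriched genes, rumen epithelium gave 42 for feed efficiency in Angus, 65 for the interaction and 641 for Angus minus Kinsella, liver 226 in Angus and 147 for the interaction, and muscle 7 for feed efficiency, 8 in Charolais and 1 for the slope on thickness; the cause was not tested.

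RLE scaling gave 75 genes in Angus rumen epithelium and 464 for the interaction there, and 2 for feed efficiency in liver. DESeq2 gave 407 in Angus rumen epithelium; 5 for feed efficiency, 667 in Angus, 6 in Charolais and 478 for the interaction in liver; 106 for feed efficiency, 6 in Kinsella, 4 in Charolais, 797 for the interaction and 20 for the slope in muscle; and 14 for feed efficiency, 3 in Kinsella, 79 in Angus, 1 in Charolais, 28 for the interaction and 2 for the slope in backfat. An additive model gave 0 for feed efficiency in liver and 0 in muscle. Thickness as a covariate gave 2 in liver and 14 in muscle. Only the libraries of 1 breed, which are fewer, gave 584 in Angus rumen epithelium, 91 in Angus liver, 3 in Kinsella, 1112 in Angus and 0 in Charolais muscle, and 1 in Angus backfat. The cause was not tested.

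With the 3 percentages of unassigned records as covariates, rumen epithelium gave 0 in Angus, 0 for the interaction, 53 for Angus minus Kinsella and 291 for Charolais minus Kinsella. Liver gave 0 for feed efficiency, 2 in Kinsella, 26 for the interaction, 2471 for breed, 3 for Angus minus Kinsella, 30 for Charolais minus Kinsella and 3141 for Charolais minus Angus. Muscle gave 55 for feed efficiency, 5 in Kinsella, 898 in Angus, 0 in Charolais, 155 for the interaction, 3716 for breed, 1355 for Charolais minus Kinsella and 2349 for Charolais minus Angus, and backfat gave 1 in Angus and 1171 for Angus minus Kinsella. The term for liver reads gave 11 for feed efficiency in muscle, 114 in Angus, 0 in Charolais, 0 for the interaction and 1115 for Angus minus Kinsella.

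Leaving out 1 Angus library at a time gave 0 to 1731 genes for Angus in rumen epithelium, 197 to 1416 in liver, 1350 to 2371 in muscle and 1 to 117 in backfat. Without rumen Angus Low steer 19, which had few counts, rumen epithelium gave 0 for feed efficiency, 0 in Kinsella and 0 in Charolais, 1172 for the interaction, 3050 for breed, and 1082, 627 and 2774 for the 3 pairs of breeds, and the enriched genes were 2964 as before.

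The difference in thickness between High and Low reversed with ranks, to 0.383 (permutation p = 0.925), both far from the threshold. A lower limit of 1 on the mean gave 5 junctions in muscle and 0 in backfat, and edgeR on recovered reads also gave 5 and 0. Without limits on mean inclusion, breed gave 9 cassette exons in rumen epithelium, 1259 in liver, 1492 in muscle and 103 in backfat, and feed efficiency gave 1 in rumen epithelium and 3 in liver; the cause was not tested.

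With the animal as a replicate block the tissue comparison gave 2991 enriched genes. For junction numbers a block in the resampling alone leaves the F at 47.54 by construction and says nothing of stability; with the animal in the model the F was 48.31 (permutation p = 1e-05, the smallest these permutations can give). In simulated data at the depth of these libraries, 74.6 to 83.6% of genes changed 1.5-fold were recovered over all breeds and 35.8 to 53.7% within Angus, a contrast of fewer steers. The simulation held no variation shared between genes, so these rates may not carry over to the real libraries. Depth itself was varied only for junction numbers, where the F was 263.8 with libraries thinned to 5054933 reads.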

Other observations

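The comparisons with permuted labels in this part were chosen only after the results were seen, and the comparison of cassette exons was added after the data were seen.

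Several features of the libraries belong to no comparison above. Exons with a value of at least 1 numbered 129950 ± 1635 (SD, n = 48) in backfat, 119730 ± 4014 (n = 47) in rumen epithelium, 111860 ± 3951 (n = 48) in liver and 100200 ± 3881 (n = 43) in muscle. Records outside genes took 39.5 ± 2.50% in backfat, 22.5 ± 7.53% in rumen epithelium, 12.8 ± 4.34% in liver and 12.4 ± 2.11% in muscle. In rumen epithelium introns with a value of at least 1 numbered 8039 ± 3047, the widest spread of the 4 tissues, and in liver 4826 ± 727. Exon and intron numbers were not thinned to an equal depth. Their order over the tissues is the reverse of that of junction reads, so depth and tissue cannot be told apart in them. Liver exon 13 of ENSBTAG00000007152 had an inclusion of 94.3 ± 1.78% against 62.2% in rumen epithelium, 56.4% in muscle and 60.5% in backfat, and exon 6 of ENSBTAG00000010799 of 25.5 ± 4.39% against at least 47.8% elsewhere.

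Labels were permuted among steers to see whether chance can be excluded. For tissue-enriched genes it can (1 of 24 splits gave 2964 genes, highest other 1). For feed efficiency in Angus it can in muscle (1779 genes, 1 of 60, highest other 162). In rumen epithelium (254 genes, 1 of 60, highest other 0) and backfat (5 genes, 1 of 60, highest other 1) no permuted split reached the count. Without Low steer 17, 20 or 21 or High steer 26 the rumen count was 0. Without Low steer 21 or High steer 27, 28, 29 or 31 the backfat count was 1. Both counts thus rest on single libraries, and the tests were not corrected for their number, so chance stays open in both. In Angus liver chance cannot be excluded, since 3 of 60 splits gave at least 438 genes and the highest other gave 500. Of the first 50 splits 2 did. For feed efficiency over all breeds chance can be excluded in muscle (31 genes, 1 of 60, highest other 1), as it can in Charolais muscle (13 genes, highest other 2), but not in liver (1 gene, 4 of 60, highest other 17). Counts of 0 are reached by all 60 splits: the highest other was 22 in rumen epithelium and 79 in backfat over all breeds. In Kinsella it was 1777 in rumen epithelium, 4 in liver, 1 in muscle and 8 in backfat, in Charolais 0, 3 and 3 in rumen epithelium, liver and backfat, and for the interaction in backfat 7. That a split of Kinsella rumen libraries called 1777 genes where the real one called 0 points to a structure of those libraries.

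For breed as a whole chance can be excluded in all 4 tissues. It can also be excluded for the pairs of breeds, except Charolais minus Kinsella and Charolais minus Angus in rumen epithelium. There a permuted split called more genes than the real one, so chance stays open. In rumen epithelium the highest other was 1665 for breed, 847 for Angus minus Kinsella, 1291 for Charolais minus Kinsella and 3025 for Charolais minus Angus, where 2 of 60 splits reached the real 600 and 2592; splits this high point to a structure of the libraries beside breed. In liver the highest other was 2532, 1 and 503 for the same pairs, in muscle 2, 1 and 2, and in backfat 1, 3 and 13, with 9 for breed in backfat. For the 537 genes called for breed in all 4 tissues 1 of 60 splits gave as many (highest other 1). No permuted split called more than 2 genes for breed in muscle, so a large overlap was not possible in them. This comparison therefore says nothing of sharing between tissues beyond the counts of each tissue.

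The direction of breed changes was compared between tissues over all 12053 genes with the same 60 splits, in which a steer keeps 1 label in all its tissues. For Angus minus Kinsella 32.2% of genes had 1 sign in all 4 tissues (1 of 60 splits, highest other 30.7%), and the median of the other splits was 16.3%. The margin over the highest other split is narrow and the tests were not corrected for their number, so chance stays open. For Charolais minus Kinsella (18%, 20 of 60, highest other 35.2%) and Charolais minus Angus (15.5%, 30 of 60, highest other 26.2%) permuted splits gave more, so chance cannot be excluded. Chance can be excluded for the correlation of log2 fold changes across genes in some pairs of tissues. In Charolais minus Angus these are rumen epithelium and liver (0.713, 1 of 60, highest other in size 0.497) and liver and muscle (-0.353, 1 of 60, 0.302). In Charolais minus Kinsella it is muscle and backfat (0.47, 1 of 60, 0.408). In Angus minus Kinsella it is rumen epithelium and backfat (0.338, 1 of 60, 0.248). For liver and backfat in Angus minus Kinsella (0.42, 1 of 60, 0.413) no permuted split gave more. The margin there is narrow and the pairs were not corrected for their number, so chance stays open. For rumen epithelium and liver in Angus minus Kinsella (0.629, 2 of 60, 0.69) a permuted split gave more, so chance stays open. It cannot be excluded for the other 12 pairs. In Angus minus Kinsella these are rumen epithelium and muscle (0.274, 8 of 60, highest other 0.35), liver and muscle (0.298, 3 of 60, 0.427) and muscle and backfat (0.243, 22 of 60, 0.385). In Charolais minus Kinsella they are rumen epithelium and liver (0.282, 8 of 60, 0.564), rumen epithelium and muscle (0.0311, 53 of 60, 0.331), rumen epithelium and backfat (0.111, 31 of 60, 0.326), liver and muscle (0.0986, 38 of 60, 0.362) and liver and backfat (0.188, 31 of 60, 0.373). In Charolais minus Angus they are rumen epithelium and muscle (-0.223, 11 of 60, 0.373), rumen epithelium and backfat (0.0958, 32 of 60, 0.306), liver and backfat (0.0615, 52 of 60, 0.305) and muscle and backfat (0.279, 11 of 60, 0.438).

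For junctions by feed efficiency permuted splits reached the real counts in muscle (11, 2 of 100 splits, highest other 12) and in backfat (1, 4 of 100, highest other 4). Chance therefore stays open in both. All 100 splits reached the 0 of rumen epithelium, where 1 gave 776, again a sign of structure in those libraries, and the 0 of liver (highest other 2). For cassette exons chance can be excluded for tissue (221, 1 of 100, highest other 29) and for breed in liver (13, highest other 2), muscle (10, highest other 0) and backfat (8, highest other 1). All 100 splits reached the 0 for breed in rumen epithelium (highest other 3) and for feed efficiency in the 4 tissues (highest others 2, 1, 1 and 3).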
